A study of Mus musculus with 4 samples.

How the data were processed

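RNA sequencing was done on heart ventricles of mice at postnatal day 14, after the atria had been removed. The labels place 4 samples in 2 groups, 2 wild type controls and 2 mutants that lost Hnrnpu through a Cre recombinase driven by the muscle creatine kinase promoter (Ckmm-Cre). Each group held 1 male and 1 female by the labels, on a mixed strain background. The labels do not state whether the animals of a group were littermates.

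The values used were those of a single table with 1 row per gene. Per the file headers, it holds RPKM (read number scaled by transcript length and by mapped reads), with 1 value by the authors for control and 1 for mutant. The same deposited table gives the ratio (fold) of mutant over control, its log2 value, a p-value and an adjusted p-value, all made by the authors. The submitters' processing notes name Bowtie 0.12.9, DESeq with no version, and the mouse build mm9, without saying which step each was used for. The annotation, the read counter, the handling of reads that match several places and the use of strand are not given in the sources used here. Because the authors gave 1 RPKM value per group, no value per animal was analysed here, and no SD or n is given beside a level.

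The table was checked before use. It holds 36814 rows, of which 12360 were listed at 0 in both groups and carried no adjusted p, leaving 24454 tested rows. In the 10320 rows with at least 1 RPKM in both groups, the ratio of the RPKM values differed from the deposited fold by at most 0.971%. The Benjamini-Hochberg adjustment recomputed over the tested rows differed from the deposited adjusted p-value by at most 0.594%. The log2 column writes the same word for a fold of 0 and for an infinite fold, so the sign was taken from the fold for the 799 rows listed at 0 in mutant and the 2733 rows listed at 0 in control. All 38 rows of the mitochondrial genome were listed at 0 in both groups. An end coordinate was missing in 1093 rows, and 153 rows repeated the symbol of an earlier row, in which case the row with the highest mean RPKM was used.

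Sequencing depth is not stated, but small RNA genes of 1 exon have a known length, so the deposited RPKM multiplied by length steps by the worth of 1 read. Among such genes seen in 1 group alone, all 102 low values in control and all 150 in mutant lay within 3% of sums of 2 step sizes, against 44.3% and 43.1% of uniformly drawn values. The 2 step sizes were the most common values of these same genes, so much of this match was fixed in advance. The relative depths read from the steps were 1.17 and 1 for the control libraries and 3.07 and 2.24 for the mutant libraries. By these steps the mutant group held 2.44 times the reads of the control group. This holds only if the authors scaled by mapped reads, since other scaling factors would set the steps in the same way. Which step belongs to which animal could not be assigned, and RPKM values of larger genes could not be turned into reads without the authors' gene lengths. To place genes of like read number side by side, RPKM was multiplied by the exonic length of a later annotation, which 90.4% of protein coding genes with at least 1 RPKM in both groups had, as a stand-in for reads.

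The design fixed before the data were examined assumed counts per sample, or at least normalized values per sample. Neither was at hand, so the planned models with replicates could not be fitted and the authors' own test, listed beforehand as an alternative, became the main result. A gene was called when its deposited adjusted p-value was below 0.05. Gene lists were fixed by hand before the data were examined. Each list with at least 5 members at a mean RPKM of at least 1 was tested with camera in limma 3.58.1 (R 4.3.3), through its version for precomputed statistics and with the planned preset correlation of 0.01. Camera used only the members at that level, whereas counts and medians cover all tested members of a list unless stated. The statistic was a signed normal score of the deposited p-value over 11292 genes, and Benjamini-Hochberg adjustment ran over 29 lists. A correlation between genes could not be estimated without values per sample, so no list call was checked that way, and fry was not run for the same reason. Fisher's exact test of called members, run first on 35 lists in 2 directions, was kept as an alternative once the fixed design had been read again, and the results of both tests had been seen by then. It used as background the 19825 genes at or above 0.0277 RPKM, the lowest mean of a called gene. Each list's median log2 fold change was also placed among 10000 random lists of the same size matched on mean RPKM in 20 bins.

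The list tests were tested on simulated data. With 20 runs over 11000 simulated genes, camera called 99 of 100 lists shifted by 1 SD and 29 of 100 shifted by 0.5 SD, with 1 of 600 unshifted lists called at either shift. Fisher's exact test, over the 19825 background genes, called 100 of 100 lists of 30 genes shifted by 3 SD and 63 of 100 shifted by 2 SD, and made 3 calls in 1500 tests of other lists at a shift of 2 SD. The tests on simulated genes were drawn as independent and say nothing of correlated genes.

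Genes named in the text followed a rule written before the data were examined. It takes Hnrnpu, the 10 largest rises and 10 largest falls among called genes with a mean RPKM of at least 5 and no predicted-gene symbol, up to 4 members of each list with the smallest adjusted p-value, sex-linked genes, and the 5 genes with the smallest deposited p-value. The part of the rule that asks both mutant animals to lie on the same side of both controls could not be applied. Any other gene named was chosen after its values had been seen. Some single members of the lists, and 1 list of cell markers, are not reported here. An implied error of a log2 fold change was computed as its size divided by the normal score of the deposited p-value, and 95% intervals use it. Coordinates are those of the deposited table (mm9). Sequences of transcripts, from the GENCODE annotation of a later build, were used by symbol only and compared with BLAST 2.17.0, requiring at least 50% of the query to align. Calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.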

Results

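The transcripts of heart ventricles were measured by RNA sequencing in 2 wild type control mice and 2 mice that lost Hnrnpu in striated muscle, all at postnatal day 14. Hnrnpu codes for hnRNP U, a nuclear protein that binds RNA and takes part in splicing and chromatin organisation. The authors' deposited table gives 1 RPKM value per group and 1 test per gene, so levels are the authors' group values with no spread of their own. By an estimate that takes RPKM as scaled by mapped reads, the mutant libraries together were 2.44 times as deep as the control libraries.

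Hnrnpu itself, on the minus strand of chromosome 1 from 180253205 to 180267928 (mm9), was listed at 32.7 RPKM in control and 15.2 RPKM in mutant ventricles. In the authors' deposited table this was a log2 fold change of -1.10 (95% interval from -2.25 to 0.05, from the implied error), with p = 0.0613 and adjusted p = 0.438, so the targeted gene did not pass the test. The sex-linked genes were above 0 in both groups. Xist, which is expressed from the inactive X chromosome of females, was listed at 14.3 RPKM in control and 10.7 RPKM in mutant. The Y-linked genes Ddx3y and Eif2s3y were listed at 9.46 and 5.83 RPKM in control and at 8.28 and 5.03 RPKM in mutant, and Kdm5d and Uty at 1.21 and 1.44 RPKM in control and 0.641 and 0.671 RPKM in mutant. Values per animal were not analysed here.

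The question of the comparison was how loss of hnRNP U changed the transcripts of the ventricle in the second week after birth. Genes of the integrated stress response, fetal and cardiac stress genes and genes of the extracellular matrix rose, while genes for cardiac ion channels fell, each by the list tests given with them. Of 24454 rows tested in the authors' deposited table, 859 passed the threshold, 497 of them higher and 362 lower in mutant. Of the called rows, 745 were protein coding, 57 were pseudogenes, 31 processed transcripts and 25 long intergenic RNAs. The smallest change that was called was 3.03-fold, and the median size of called changes was 2.41 on the log2 scale. Of the called genes, 15 were listed at 0 in control and 7 at 0 in mutant.

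**Figure D1:**
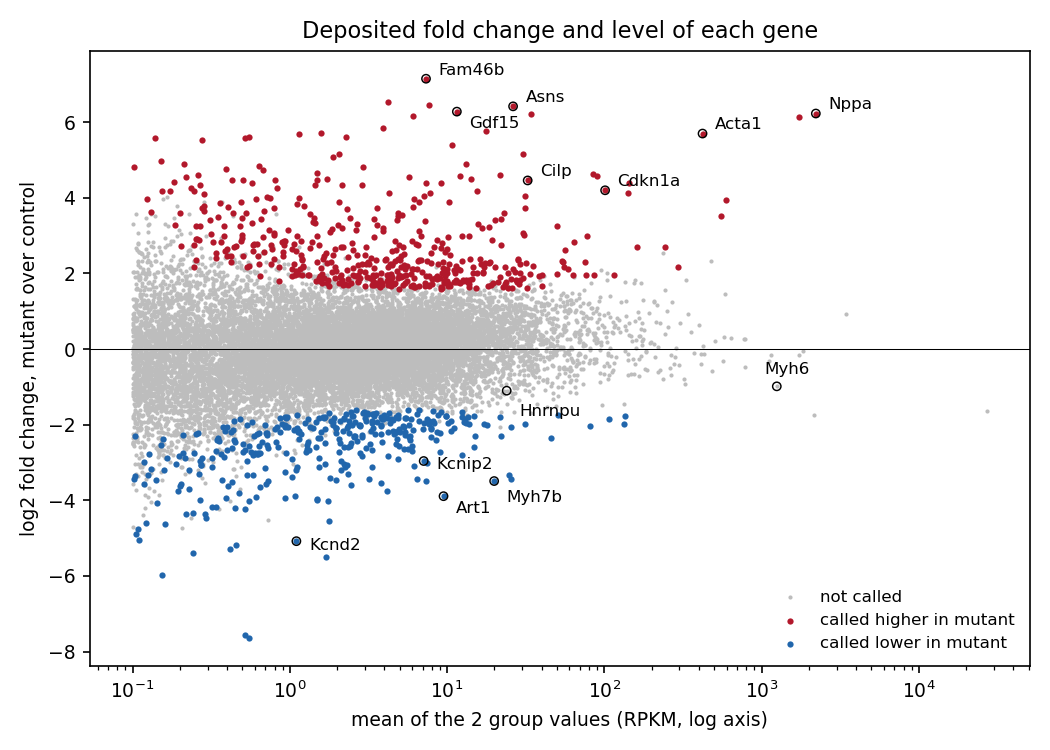
Each point is 1 gene of the authors' deposited table, with the mean of the control and mutant RPKM on a log axis and the log2 fold change of mutant over control on the vertical axis. Genes listed at 0 in 1 group or with a mean below 0.1 RPKM are not drawn. Red points were called higher and blue points lower at an adjusted p-value below 0.05, and circles mark genes named in the text; Hnrnpu, at -1.10, lies among the genes not called.

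The largest rise among called genes with a mean of at least 5 RPKM and a value above 0 in control was that of Fam46b (chromosome 4, 133036047 to 133043853), a poly(A) polymerase of the TENT5 family, from 0.102 to 14.6 RPKM, which the authors' deposited table gives as 142-fold with adjusted p = 3.15e-22. Asns, asparagine synthetase (chromosome 6, 7625169 to 7643254), rose from 0.607 to 52.0 RPKM, and Mthfd2, a mitochondrial enzyme of folate metabolism, from 0.909 to 67.1 RPKM. The authors' deposited table lists these as 85.7-fold and 73.8-fold. Gdf15, a secreted stress cytokine (chromosome 8, 73153292 to 73156355), rose from 0.295 to 22.8 RPKM. Serpina3n, a secreted protease inhibitor, rose from 0.638 to 34.7 RPKM, and Wisp2, a secreted matricellular protein, from 0.499 to 20.9 RPKM. Slc7a5, a transporter of large neutral amino acids, rose from 0.865 to 25.7 RPKM. Among abundant transcripts, Nppa, which codes for atrial natriuretic peptide (chromosome 4, 147374831 to 147376188), rose from 58.2 to 4370 RPKM, and Acta1, skeletal muscle actin, from 15.9 to 827 RPKM. In the authors' deposited table the Nppa change was 6.23 on the log2 scale with adjusted p = 0.00167, and its 95% interval was wide, from 3.37 to 9.10.

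The falls among genes with a mean of at least 5 RPKM were led by Art1, an ADP-ribosyltransferase of muscle (chromosome 7, 109250257 to 109259662), from 17.8 to 1.20 RPKM. The authors' deposited table gives it a log2 fold change of -3.89 and an adjusted p of 7.11e-09. Myh7b, a slow-type myosin heavy chain (chromosome 2, 155436948 to 155460043), fell from 36.6 to 3.27 RPKM. Rnf207, a regulator of cardiac repolarisation, fell from 44.9 to 4.42 RPKM, Kcnip2, a subunit of the channel for the transient outward potassium current, from 12.6 to 1.61 RPKM, and Aplnr, the apelin receptor, from 21.9 to 3.16 RPKM. Lgals4, a galectin, fell from 46.8 to 4.30 RPKM, Ybx2, a nucleic acid binding protein, from 13.4 to 1.21 RPKM, and Tesc, a calcium-binding protein, from 15.7 to 2.40 RPKM. Asb14 fell to 1.30 RPKM, a fold of 0.118 in the authors' deposited table. Sned1 fell from 11.8 to 1.09 RPKM, and it overlaps Mterfd2 on the other strand, which was also called, so reads of these genes could not be told apart without strand.

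Genes of the integrated stress response, the program that follows phosphorylation of the initiation factor eIF2 and includes the targets of Atf4, showed the highest count of rises. Of 34 measured members, 26 rose, none fell and 8 did not pass the test; adjusted over the list alone, 26 rose. Besides Asns, Mthfd2 and Gdf15, Phgdh, the entry enzyme of serine synthesis, rose from 0.134 to 7.72 RPKM, and Atf4 itself rose from 25.7 to 125 RPKM. Psat1, the next enzyme of serine synthesis, rose from 0.971 to 23.2 RPKM, and Fgf21, a secreted metabolic hormone, was listed at 0 in control and 5.88 RPKM in mutant. Ddit3, a transcription factor of the same program, was listed at 4.46 RPKM in control and 4.08 RPKM in mutant and did not pass the test, and Atf3 at 4.46 and 4.32 RPKM. Camera placed the list higher with adjusted p = 1.46e-39 over 31 members. Genes of the unfolded protein response of the endoplasmic reticulum gave 0 calls among 21 members in the authors' deposited table, also when adjusted over the list alone, and 2 members had an unadjusted p under 0.05, with Atf6 at 2.81 RPKM in control and 6.87 RPKM in mutant (p = 0.0108, adjusted p = 0.167). The camera test of that list gave adjusted p = 0.265.

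Genes that mark the fetal heart or cardiac stress rose together, with 13 of 22 members higher, none lower and 17 higher when adjusted over the list alone. Besides Nppa, Acta1 and Gdf15, Spp1, which codes for osteopontin, rose from 0.329 to 4.28 RPKM, Ankrd2 was listed at 0 in control and 3.35 RPKM in mutant, and Nppb, brain natriuretic peptide, rose from 72.4 to 1120 RPKM. Myh7, the fetal isoform of myosin heavy chain in mouse ventricles, was listed at 40.5 RPKM in control and at a fold of 0.618 in the authors' deposited table (p = 0.355, adjusted p = 0.897), and did not pass the test. The list's median log2 fold change was 2.23, and camera gave adjusted p = 2e-18. Nppa overlaps Gm13054 on the other strand, which was listed at 48.4 RPKM in control and 3420 RPKM in mutant.

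Genes of the extracellular matrix rose in 15 of 44 members and fell in none, with 21 higher when adjusted over the list alone. Thbs4, thrombospondin 4, rose from 1.66 to 59.5 RPKM, Cilp from 2.84 to 62.3 RPKM, Col12a1, a collagen, from 0.270 to 5.49 RPKM, and Ltbp2, a protein that binds fibrillin, from 0.820 to 13.5 RPKM. Camera gave the list adjusted p = 3.41e-17. Beside it, fibroblast markers gave 0 calls among 14 members in the authors' deposited table, 2 rises when adjusted over the list alone and 5 members with an unadjusted p under 0.05, with Tcf21 at 8.47 RPKM in control and 24.0 RPKM in mutant (p = 0.00278, adjusted p = 0.0677). The median of these markers was 0.80, and camera gave adjusted p = 0.159, but called them higher with no filter on RPKM (adjusted p = 0.0321); 6 of the 14 are also in the matrix list. Macrophage markers had a median of 1.05, and camera called them higher.

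Genes of the p53 response and apoptosis rose in 10 of 28 members, with none lower and 12 higher when adjusted over the list alone. Cdkn1a, the cell cycle inhibitor p21, rose from 10.4 to 192 RPKM, Phlda3 from 3.55 to 33.3 RPKM, Sesn2 from 0.813 to 8.73 RPKM, and Pmaip1, which codes for the apoptosis protein Noxa, from 0.0486 to 1.30 RPKM. Sesn2 is also in the integrated stress response list. Camera gave adjusted p = 3.52e-08. Of the genes of protein breakdown and atrophy, 5 of 31 rose and 9 rose when adjusted over the list alone, among them Gabarapl1 and Sqstm1, which act in autophagy, from 5.72 to 27.4 RPKM and from 22.0 to 95.9 RPKM. Bnip3 rose from 5.34 to 24.1 RPKM and Hspb1 from 8.76 to 27.7 RPKM, and camera gave the list adjusted p = 8.22e-06.

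Genes for cardiac ion channels fell in 8 of 28 members and rose in 2, with 10 lower and 2 higher when adjusted over the list alone. Kcnd2, which codes for the pore of the transient outward potassium channel Kv4.2 (chromosome 6, 21165503 to 21679805), fell from 2.14 to 0.0633 RPKM, for which the authors' deposited table gives a log2 fold change of -5.08 and an adjusted p of 1.02e-11. Kcnj3, a subunit of the muscarinic potassium channel, fell from 3.28 to 0.306 RPKM, and Scn4a, the sodium channel of skeletal muscle, from 0.739 to 0.0479 RPKM. Kcnj2, Kcne1, Kcnd3 and Kcnj5 also fell, whereas Scn4b, a sodium channel subunit, rose from 0.0533 to 0.353 RPKM. Camera placed the list lower with adjusted p = 3.52e-08. Of 27 genes of calcium handling, Casq1, the skeletal muscle calsequestrin, rose from 6.59 to 164 RPKM, and Camk2a and Cacna1h fell, from 3.93 to 0.481 RPKM and from 1.58 to 0.377 RPKM. Adjusted over the list alone, 1 rose and 7 fell, and camera gave adjusted p = 0.0708, but called the list lower with no filter on RPKM (adjusted p = 0.0321). Casq1 and Scn4a each overlap another called row on the other strand.

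Camera placed the lists of fatty acid oxidation and oxidative phosphorylation lower and that of glycolysis higher. Of 36 genes of fatty acid oxidation 3 fell and none rose, with 5 lower when adjusted over the list alone. The 3 were Ppargc1b, a coactivator, from 14.8 to 3.18 RPKM, Ucp3, a mitochondrial carrier, from 9.16 to 2.28 RPKM, and Etfb, the electron transfer flavoprotein beta subunit, from 168 to 46.9 RPKM. The median log2 fold change of this list was -0.68, and camera gave adjusted p = 0.000115, against 0.189 by Fisher's exact test of called members. Of 50 nuclear genes of oxidative phosphorylation 1 fell, Cox7a1, a muscle isoform of a cytochrome c oxidase subunit, from 130 to 31.5 RPKM, and the same 1 when adjusted over the list alone. Their median was -0.24, and camera gave adjusted p = 0.00968, against 1 by Fisher's exact test. Of 25 genes of glycolysis, the lactate transporter Slc16a3, the glucose transporter Slc2a1 and Pfkp rose, from 0.570 to 6.25 RPKM, from 1.33 to 8.14 RPKM and from 4.47 to 15.4 RPKM. Adjusted over the list alone, 6 rose and 1 fell. The median of the glycolysis list was 0.94, and camera gave it adjusted p = 0.00347, but 0.283 among genes with a mean of at least 5 RPKM and 0.186 by Fisher's exact test. In the citric acid cycle list 1 of 20 genes rose, Pcx, pyruvate carboxylase, from 0.538 to 2.10 RPKM, also when adjusted over the list alone, and camera gave adjusted p = 0.937.

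Genes for the sarcomere of the adult heart gave 1 call among 25, also when adjusted over the list alone: Synpo2l rose from 17.4 to 138 RPKM. Des, which codes for desmin, was listed at 69.5 RPKM in control and 404 RPKM in mutant and did not pass the test. Myh6, the adult myosin heavy chain, was listed at 1660 RPKM in control and 840 RPKM in mutant, also without a call. Its 95% interval, from the implied error, ran from -7.3 to 5.3 on the log2 scale. The lack of calls among such abundant genes therefore does not show that they were unchanged. Camera gave the sarcomere list adjusted p = 0.534. Among cardiac transcription factors 1 of 28 fell, Hopx, from 78.7 to 23.5 RPKM, with 1 higher and 1 lower when adjusted over the list alone and camera at adjusted p = 0.856.

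The series title names splicing, so genes for splicing factors and genes known for splicing changes in the heart were listed too. Of 53 splicing factors 1 fell, Rbfox1, a regulator of alternative exons, from 5.54 to 0.979 RPKM, and the same 1 when adjusted over the list alone. Rbm20, the splicing regulator of titin, was listed at 30.2 RPKM in control and 11.2 RPKM in mutant, and Hnrnph1 at 35.2 and 13.0 RPKM, neither with a call. The median of the list was -0.42, with 39 members below control and 14 above, and camera gave adjusted p = 0.000659, against 1 by Fisher's exact test. The 36 genes spliced in a heart-specific way gave 0 calls and 9 members with an unadjusted p under 0.05 in the authors' deposited table, with Speg at 35.2 RPKM in control and 8.36 RPKM in mutant (p = 0.00229, adjusted p = 0.0594). Adjusted over the list alone, 2 rose and 2 fell, and camera gave adjusted p = 0.379, whereas the median of -0.26 lay at percentile 0.055 of random lists matched on RPKM. Values per exon or isoform were not analysed here, so splicing itself was not measured.

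**Figure D2:**
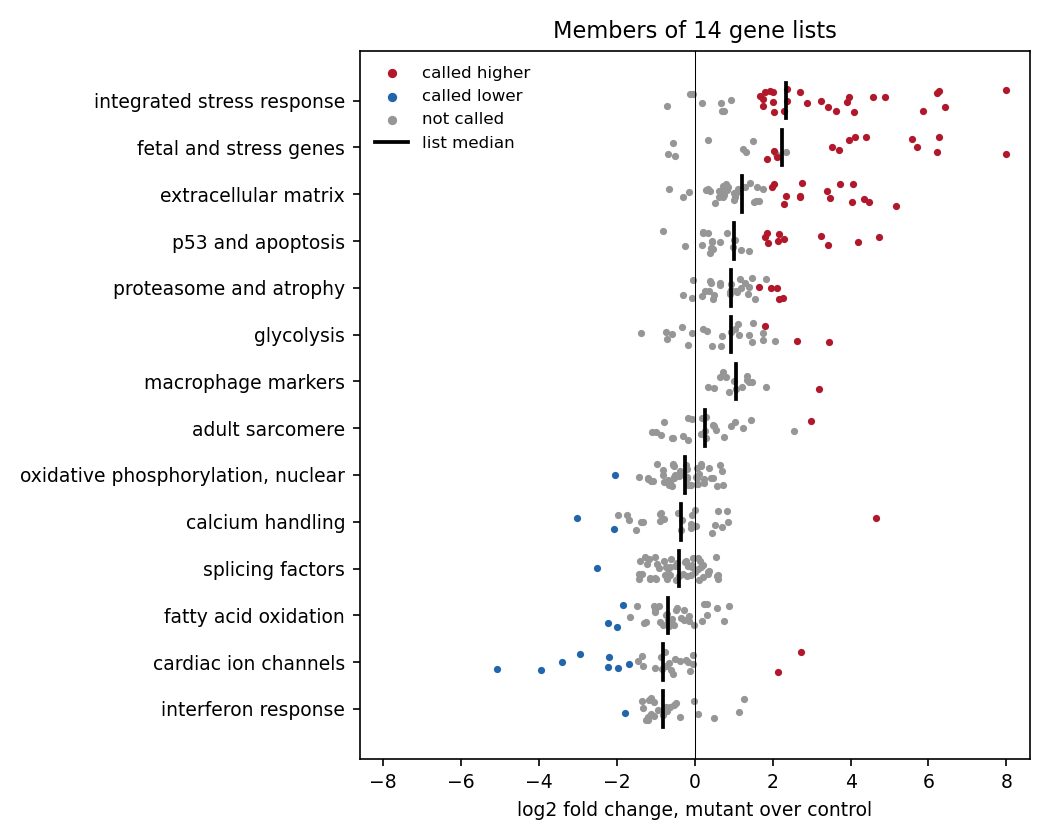
Each point is 1 member of a fixed gene list, at its log2 fold change of mutant over control in the authors' deposited table, and the black bar is the list's median. Red points were called higher, blue points lower and grey points not called; Fgf21 and Ankrd2, listed at 0 in control, are drawn at 8. The integrated stress response list has its median at 2.33 and the cardiac ion channel list at -0.80.

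Of 26 interferon response genes Rsad2 fell from 3.87 to 1.12 RPKM, also when adjusted over the list alone. Camera placed the list lower with adjusted p = 0.00123 over 14 members, against 1 by Fisher's exact test. Of 43 cell cycle genes Ccnd1, cyclin D1, fell from 15.2 to 4.48 RPKM, likewise over the list alone, with camera at adjusted p = 0.0821, and at 0.045 on ranks. Of 21 hypoxia and angiogenesis genes Hif3a, Bnip3 and Hmox1 rose and Aplnr fell, and 4 rose and 1 fell when adjusted over the list alone, with camera at adjusted p = 0.466. Of 21 growth and imprinted genes Igf1r rose from 1.87 to 6.48 RPKM, with 3 higher and 1 lower when adjusted over the list alone and camera at adjusted p = 0.856. The ribosomal protein and replication histone lists gave 0 calls among 35 and 27 members in the authors' deposited table, also when adjusted over each list alone. In each list 2 members had an unadjusted p under 0.05, and camera gave adjusted p = 0.361 and 0.937, over 25 and 5 members. With no filter on RPKM camera called the ribosomal protein list higher (adjusted p = 0.0493).

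Markers of the cell types of the ventricle differed in the direction of their medians. Macrophage markers were above control in all 15 members, with a median log2 fold change of 1.05. Lgals3 rose from 0.420 to 3.85 RPKM, and 4 macrophage markers rose when adjusted over the list alone. For these markers camera gave adjusted p = 0.000659 over 11 members, but 0.0567 among genes with a mean of at least 5 RPKM. Fisher's exact test gave 1. C1qa and C1qb, complement genes of macrophages, were listed at 15.7 and 16.1 RPKM in control and at 40.1 and 42.4 RPKM in mutant without a call. Endothelial markers had a median of -0.33, with 1 call of 15, Vwf, from 1.54 to 7.79 RPKM, and camera gave adjusted p = 0.856. Mural cell markers gave 1 call of 12, Tagln, from 9.76 to 42.6 RPKM, with adjusted p = 0.518 for the list. The 12 cardiomyocyte markers gave 0 calls in the authors' deposited table and a median of -0.31, with 1 member at an unadjusted p under 0.05, Ryr2, at 52.2 RPKM in control and 16.3 RPKM in mutant (p = 0.0461), and camera gave the list adjusted p = 0.55. The medians of the cardiomyocyte and endothelial markers lay at percentiles 1.08 and 1.09 of random lists matched on RPKM. Atrial markers were split, as Nppa and Dkk3 rose and Kcnj3 fell, and camera gave adjusted p = 0.798 over 10 members; the 5 with a mean of at least 5 RPKM had a median of 1.84 and adjusted p = 0.0564. Erythroid markers gave 0 calls of 9 in the authors' deposited table. The 1 member with an unadjusted p under 0.05 was Alas2, at 5.92 RPKM in control and 16.5 RPKM in mutant. For this list camera gave adjusted p = 0.104 over 5 members, but 0.0258 with no filter on RPKM and 0.045 on ranks. Adjusted over each list alone, 1 endothelial and 1 erythroid marker rose, 3 mural markers rose and 1 fell, 3 atrial markers rose and 2 fell, and 0 cardiomyocyte markers passed.

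The lists with fewer than 5 members at 1 RPKM were counted without camera. Of 18 skeletal muscle markers, Myl1 and Mybpc2 rose from 0.145 to 3.29 RPKM and from 2.31 to 13.6 RPKM, and Tnni2 fell from 1.03 to 0.0633 RPKM. The epicardial keratin genes Krt8 and Krt19 rose from 0.0523 to 1.09 RPKM and from 0.212 to 1.34 RPKM, among 9 epicardial markers. Tubb3 rose from 0.501 to 6.67 RPKM among 10 neural markers. Neutrophil and adipocyte markers gave 0 calls of 10 and 7 in the authors' deposited table, also when adjusted over each list alone, and 0 and 1 members had an unadjusted p under 0.05, with S100a9 at 1.72 RPKM in control and 3.20 RPKM in mutant and Fabp4 at 339 and 255 RPKM. Adjusted over each list alone, 2 skeletal muscle markers rose and 2 fell, and 4 epicardial and 2 neural markers rose. With no filter on RPKM camera called the epicardial and neural lists higher, with adjusted p = 0.0155 and 0.00628.

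The p-values rest on 2 animals per group, and implied errors differed little between genes of like level and length, so a called rise does not show that both mutant animals changed. The same holds for the lists, since camera took its scores from these p-values and used a preset correlation between genes. Its p-values compare the members of a list with other genes. They do not measure replication over animals, however small they are. Genes above 300 RPKM had a median implied error of 0.98 on the log2 scale against 0.52 between 3 and 10 RPKM, and the smallest change called above 300 RPKM was 3.52.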

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

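No paired analysis was possible because the deposited table gives 1 value per group and no value per animal. For the same reason TMM, size factors and library totals, leaving out each animal, pseudocounts, limma-voom and the other count models, a test against a 1.5-fold change, fry and camera with an estimated correlation were not run. The thresholds of 0.01 and the RPKM filters were planned; the threshold of 0.1, protein coding rows alone, overlapping rows counted once, recentring, counting overlaps once near Hnrnpu, camera on ranks or protein coding genes and Fisher's exact test were chosen after seeing the data. The count of 859 called rows became 497 at an adjusted p of 0.01 (306 higher, 191 lower) and 341 among genes with a mean of at least 5 RPKM (247 higher, 94 lower), which tests fewer genes. That last filter moved the share of rises among calls from 57.9% to 72.4%; the other alternatives gave 712 to 1203 calls. Hnrnpu stayed without a call, at adjusted p from 0.278 to 0.438, with a log2 fold change of -1.17 after recentring. Camera called 12 lists, 19 with no filter on RPKM and 9 to 14 in its other settings; Fisher's exact test called 6, all of them among the 12, and did not call fatty acid oxidation, glycolysis (adjusted p = 0.189 and 0.186), oxidative phosphorylation, splicing factors, interferon response or macrophage markers (1 each). No list changed direction past its threshold in camera. Glycolysis and macrophage markers lost their call at a mean of at least 5 RPKM (adjusted p = 0.283 and 0.0567), and the interferon list had too few members there to be tested. Calcium handling, ribosomal proteins, fibroblast and erythroid markers gained one with no filter (0.0321, 0.0493, 0.0321 and 0.0258), and cell cycle genes and erythroid markers on ranks (0.045 each). The cause was not tested. Among lists that camera did not call, the median lay outside the central 95% of random lists matched on RPKM for calcium handling, heart-spliced genes, cardiomyocyte and endothelial markers (percentiles 0.18, 0.055, 1.08 and 1.09) and for hypoxia, ribosomal protein and fibroblast lists (98.2, 97.8 and 97.8). Of the named genes that stayed in under a filter no call was lost and 19 gene and filter combinations gained one, since fewer genes were tested. Depth limits the control values more than the mutant ones if the control libraries were shallower, as the estimate of depth gives.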

Other observations

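Tests of the fall of the whole respiratory chain list, the size of change that the test called, a library of wild type RNA, cells without the recombinase, the sex of the libraries and gene span were chosen after their results were seen, as were the counts of pseudogenes, coding genes like them and overlapping rows. The tests of sequence identity and of the surroundings of nuclear mitochondrial copies were written down beforehand for fewer copies, and were reworded with their bounds kept once 10 copies with a value had been found. The tests of a fitted spread and the chromosome around Hnrnpu were written down beforehand.

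Transcripts that match the mitochondrial genome were lower in mutant ventricles, although the 38 rows of that genome were listed at 0. Of 21 nuclear pseudogenes of a later annotation that align to mitochondrial genes, 11 matched no row by symbol and were not analysed here. Of the 10 with a value, 9 were called lower and none higher, with log2 fold changes from -1.78 to -2.60 in the authors' deposited table; these genes were chosen after their values were seen. The copy of mt-Co1 on chromosome 2, Gm13340 (97.6% identical), was listed at 212 RPKM in control and 53.5 RPKM in mutant, and the copy of mt-Atp6 on chromosome 1, Gm10925 (100% identical), at 211 and 61.6 RPKM. Gm11408, a copy of mt-Nd6, was listed at 25.6 RPKM in control and 4.23 RPKM in mutant.

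These rows may hold reads of mitochondrial transcripts placed on nuclear copies. The control level rose with sequence identity over the 10 copies with a value (Spearman's rho = 0.815, permutation p = 0.00628, adjusted over 3 tests p = 0.00942), although neighbouring copies are not independent. A common fall of the chromosomal surroundings is argued against, since the 9 other tested genes within 200 kb had a median log2 fold change of 0.21 (quartiles from -0.85 to 1.14). None of these neighbours was called, which says little, as only 3.51% of all tested rows were called. The neighbours were pooled over the places of the copies, so a change at a single place is not excluded. A like fall of all transcripts for the respiratory chain is also argued against by the nuclear list, with a median of -0.24 and a lower quartile of -0.63, above the smallest fall of the copies. Whether mitochondrial RNA itself fell with the genotype, or libraries differed in how much of it they captured, stays open.

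Hnrnpu kept 46.5% of its control level in mutant ventricles without a call. The smallest change called among the 867 genes within 1.5-fold of its level was 1.61 on the log2 scale, above the 1.10 by which Hnrnpu fell. The smallest change called at any level was 1.6, so a change of the size of that of Hnrnpu was called for no gene. This comparison could not have come out otherwise and tests no explanation of the missing call. RNA from ventricle cells in which the recombinase was not active could supply the remaining transcripts, and no value per cell type or exon tests this. A mutant library made of wild type RNA would keep genes at or above the share of the group value that 1 library holds. By the relative depths this share is at least 42.2%, the value if reads were pooled before scaling. Libraries scaled 1 by 1 and then averaged, as 2 step sizes per group would require, would hold equal shares, near the 46.5% that Hnrnpu kept. Of 4186 genes with at least 5 RPKM in control, 6 lay below 42.2% at a one-sided adjusted p (Benjamini-Hochberg, from the implied errors) under 0.05. The number of genes asked for was lowered after this count was seen, so the count decides nothing. These 6 genes, among them Art1 and Lgals4, kept a median of 8.76% of control, but they were singled out by their low values. The implied errors carry little of a gene's own spread, so neither such a library nor a smaller admixture is excluded.

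Sex-linked genes had implied errors near those of genes of like level, although each group held 1 male and 1 female by the labels, so that Xist and Y-linked genes should differ widely within a group. Their implied errors were 0.904 (Uty) to 1.10 (Xist) times the median of such genes, with Xist, Ddx3y and Eif2s3y above it at percentiles 91.3, 89.5 and 81.2 and Kdm5d and Uty below it at 31.1 and 20.8. A candidate explanation is a test that used a spread fitted over genes of like level in place of each gene's own. This was examined over 4987 protein coding genes, kept only where the p-value was neither large nor very small. The implied error deviated from that of the 20 nearest genes by RPKM times exonic length by a median of 1.87%, with a 95th percentile of 9.09%. The median deviation from a random gene of this set was 4.81%, so errors differed little between any of these genes. The larger of own and fitted spread with 2 samples per group would give a 95th percentile of 73.1%. That value holds without the limit on p, which removes genes with large errors, so the 2 percentiles are not strictly alike. A group whose libraries were all of 1 sex is argued against, as Xist and Ddx3y were at 8.28 RPKM or more in both groups. Libraries that each held RNA of both sexes stay open without values per animal, as all 5 sex-linked genes were above 0 in both groups, and no biological explanation was tested.

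The strain of the chromosome around the targeted gene is a further hypothesis, as the animals were of mixed background. Of 378 tested genes within 20 Mb of Hnrnpu, 5.56% were called, against 3.48% elsewhere (Fisher's exact test, two-sided, p = 0.0465, adjusted over 3 tests p = 0.0465). They may include differences of strain, such as Mndal, of the interferon-inducible cluster, which fell from 9.60 to 1.95 RPKM, overlaps the called gene Ifi203 on the same strand and was named after its values were seen. With overlapping called rows counted once, the shares were 5.05% and 3.37% and Fisher's exact test gave p = 0.0831, above 0.05, so the hypothesis stays open.

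Long genes tended to be lower in mutant. Across 10161 protein coding genes, which are not independent replicates, Spearman's rho of gene span with log2 fold change was -0.118 (permutation p = 1e-04, the smallest that 10000 permutations can give; adjusted over 3 tests p = 0.0003). The rho was below 0 in all 5 bins of genes by mean RPKM, from -0.137 to -0.026. The median log2 fold change was 0.19 among genes with a span up to 4.11 kb, 1 of 10 bins by span, and -0.14 in the bin with the longest span. Gene span here is the genomic extent with introns and not the length of the mature transcript. Whether the trend reflects long genes in mutant ventricles or RNA quality was not tested, and no value per library separates these.

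Some called rows resemble or overlap other rows, and whether they shared reads was not tested. Of 57 called pseudogenes, 35 aligned to a protein coding gene with at least 90% identity, and for 10 of these the coding gene was called in the same direction. The coding gene was not called for the other 25, and in 4 of them it lay on the other side of control, such as Aph1a at 9.61 and 6.92 RPKM beside Gm15429 at 1.87 and 7.01 RPKM in control and mutant. Gm7901, among the 5 smallest p-values of the authors' deposited table, is 98.8% identical to Phgdh. Of 848 called rows with both coordinates, 277 (32.7%) overlapped another tested row, against 36.4% of rows not called, and 28 of 30 overlapping pairs of called rows moved in the same direction. The row AL928940.2, listed as a microRNA, held 41100 RPKM in control and 13200 RPKM in mutant, and Lars2 held 3320 and 992 RPKM, both without a call.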
